A study of Danio rerio with 36 samples.

How the data were processed

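Messenger RNA of caudal fins and of sorted fin fibroblasts was measured by RNA-seq with a stranded library kit, per the labels' protocols, in 18 libraries. The deposited values are whole read counts per gene, 1 set per library, with 14781 gene symbols and 5 summary entries that name htseq-count, per the file headers and values. Per the submitters' processing notes, the tools were Trim Galore (0.6.4 and 0.4.1), TopHat2 2.1.1, HTSeq 1.6.1, Bowtie2 2.2.5, SAMtools 1.5, Picard 1.91 and MACS2, with the danRer10 genome build; the notes give no order and do not tie each tool to an assay. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Counts of near-identical genes, such as those of the keratin, mpeg1, chemokine, globin, actinodin and myosin families, depend on how shared reads were treated and are uncertain. Reads on no annotated gene made up 26.5 to 39.0% of the reads of a library and ambiguous reads 0.246 to 0.645%; both stayed out of library sizes and tests. Total gene counts ranged from 19427984 to 43871436 per library. The 18 accessibility (ATAC-seq) samples of the 36 in the series were not analysed here. All count columns were mapped to their samples.

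Groups follow the labels. For batch 2 the names under which the data were deposited give the 0 and 1 dpa groups the other way round; the labels were followed, and these libraries are called "labelled 0 dpa" and "labelled 1 dpa". The labels of the fibroblast samples name different transgenes in the growth and treatment protocols, and the sort is described only in the part on accessibility. Tissue dissociation is described for the samples of both assays. Gene names are those of the deposited data. A gene table of the assembly GRCz12tu was used only for current names, older names and the neighbours of lepb; 14519 of 14781 symbols matched it, 12660 as current symbols.

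Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM scaling, its expression filter, two-sided, Benjamini-Hochberg adjustment over tested genes, called at an adjusted p under 0.05) in R 4.3.3. The replicated comparisons were whole fins at 4 against 0 dpa (batch 1), labelled 1 against 0 dpa (batch 2) and sorted fibroblasts at 4 against 0 dpa (batch 3), each fitted on its own libraries without covariates. Differences of responses were contrasts of 4 groups in 1 fit with a mean per group. The 22 gene lists were written from textbook knowledge and tested with camera (limma 3.58.1) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Of 712 list genes 589 were found, 20 of them by an older symbol. With the estimated correlation the blastema list in the difference between batch 1 and batch 2 kept its call. So did the osteoblast list of that difference with the groups of batch 2 exchanged. The other lists called with the preset correlation lost it. With an estimated correlation camera also uses the few residual degrees of freedom of the fit. A lost call therefore need not mean correlated genes. The blastema list of whole fins at 4 dpa lost its call at an estimated correlation of -0.0266. CPM values use the TMM factors of all 18 libraries unless stated; CPM of the single libraries in the LEN comparison use factors of those 4 libraries.

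Named genes were picked by a rule: per replicated comparison the 8 largest increases and 6 largest decreases in log2 fold change among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out symbols that are clone identifiers; 16 genes chosen in advance for their role in fin regeneration; and up to 3 members of each list with the smallest p. Differences of responses add the 5 largest each way. For single libraries the rule took the 5 largest ratios each way, with a prior count of 2, among genes with at least 50 counts in the higher library, the 16 genes and those within 200 kb of lepb. Genes picked after their values were seen are said to be so. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except the exchange of the batch 2 groups. A fold with 1 to 3 counts in a group was computed from counts with an exact conditional 95% interval, and against 0 counts from a floor of 3 counts over the group.

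With 1 library per group, CPM values have exact Poisson 95% intervals, and log2 ratios exact conditional intervals that cover counting error only. Lists were placed by the percentile of their median log2 ratio among 10000 random lists of the same size, matched on mean expression in 20 bins, over genes with at least 40 counts in the 4 libraries. Genes of a random list were drawn independently, so the percentiles take no account of list members that vary together.

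Alternatives were DESeq2 size factors, scaling by library size only, no expression filter, the DESeq2 1.42.0 and limma-voom tests, 1 fit of all replicated groups, the replicate number as a block and leaving out each replicate; for single libraries, 2 scalings, a prior count of 0.5 and the mean of a list. The tests were tried on simulated data with 200 changed genes. Each comparison of the data called far more genes than that, which makes its adjusted threshold less strict than in the simulation. The recovered and false shares below therefore describe the simulation only. For the comparison of whole fins at 4 dpa, with each gene keeping its own fitted dispersion, 27.3, 82.8 and 97.0% of genes changed by 0.5, 1 and 2 (log2) were recovered over 11819 genes, and 18.2% of the calls were false. Recovery for these sizes was 60.6, 90.8 and 96.9% for batch 2 and 0, 46.2 and 83.3% for fibroblasts. It was 1.52, 15.4 and 78.1% for the fibroblast and whole-fin difference. For the difference between batch 1 and batch 2 it was 12.1, 72.7 and 85.9%. False shares were 8.99% for batch 2 (11799 genes), 9.57% for fibroblasts (11984), 14.1% for the fibroblast and whole-fin difference (12260) and 8.26% for the difference between batch 1 and batch 2 (12086). Dispersions taken from the fitted trend, a mode added after the other was seen, gave 4.86, 5.68, 5.45, 3.85 and 3.60% in that order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.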

Results

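The series followed regeneration of the zebrafish caudal fin, an appendage that regrows its bony rays, connective tissue and skin after amputation. Messenger RNA was counted per gene in 18 libraries of EK-strain fish. The series holds 36 samples, and its 18 chromatin accessibility samples were not analysed here. Per the labels, batch 1 held whole fins that were uninjured (0 days post amputation, dpa; n = 2) or at 4 dpa (n = 2). Batch 2 held whole fins labelled 0 dpa (n = 3) or 1 dpa (n = 3). Batch 3 held sorted fibroblasts at 0 dpa (n = 2) and 4 dpa (n = 2). The same batch had 1 whole-fin library for each of wild type and LEN deletion at 0 and 2 dpa. LEN is the lepb-linked enhancer, a stretch of noncoding DNA known from earlier work as a regulator of the leptin gene lepb after injury. Per the treatment protocol, the fibroblasts were marked through a transgene driven by tph1b, a gene active in fin fibroblasts. Tamoxifen was given at 4 µM for 12 h from 2 dpa, and the fins then regrew before use. The growth protocol names a different transgene. Each whole-fin sample pooled 15 fish and each fibroblast sample 75 fish.

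In batch 1 the 0 dpa libraries held 19427984 and 26559399 gene counts and the 4 dpa libraries 31657833 and 31619625. The libraries labelled 0 dpa in batch 2 held 36379979, 38064840 and 36864486 and those labelled 1 dpa 30453219, 32784365 and 34202552. Fibroblast libraries reached 43871436 and 41375969 at 0 dpa and 36522921 and 39205798 at 4 dpa. Single whole-fin libraries of batch 3 held 25367791 (wild type, 0 dpa), 26284707 (deletion, 0 dpa), 28679133 (wild type, 2 dpa) and 27994720 (deletion, 2 dpa) gene counts. The keratin gene krt5 took 3.53 to 10.3% of the counts of a whole-fin library. In sorted fibroblasts the top gene was the heat shock gene hsp70.1 at 0 dpa (3.67 and 5.08% of counts) and the collagen gene col1a1a at 4 dpa (4.83 and 6.51%). Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 14.4 to 121 and a Spearman correlation of 0.987 to 0.996, so they were not repeat reads of 1 library; that each is a sample of its own rests on the labels. The labels describe triplicate pools of fish, which here number 2 or 3 per replicated group, and say nothing more on how the pools were drawn. The p-values therefore measure the spread between these pools. Levels are given below in TMM-normalised counts scaled to library size (CPM) as mean ± SD over the libraries of a group. The median of a gene list is that of its members' log2 fold changes, and values in brackets after a gene name are log2 fold changes unless said otherwise.

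The comparison of whole fins at 4 dpa with uninjured fins of batch 1 asked which genes accompany outgrowth of the regenerate. Regenerating fins carried far more transcript of and1 and and2, which encode actinodin proteins of the fibrils at the growing fin edge. They stood at 6009 ± 421 and 2501 ± 92.1 CPM (n = 2) against 43.9 ± 0.472 and 12.2 ± 2.01 CPM (n = 2) at 0 dpa. The bone and tooth matrix genes scpp5 and scpp7, all 18 blastema genes and 45 of 46 cell cycle genes rose with them, while 31 of 40 epidermal, 12 of 19 nerve and glial and 18 of 27 stress genes fell. With an estimated correlation, a test that rests on few residual degrees of freedom, no list of this comparison kept its call. The tenascin gene tnc, a matrix gene of the blastema, rose from 12.8 ± 2.1 to 1072 ± 68.3 CPM (log2 fold change 6.28, SE 0.206, edgeR adjusted p = 1.88e-07). The leptin gene lepb rose from 0.302 ± 0.171 to 32.5 ± 7.71 CPM (log2 fold change 6.66, SE 0.319, edgeR adjusted p = 6.14e-07). By edgeR's quasi-likelihood test, 7805 of 11912 genes tested differed at an adjusted p under 0.05, of which 3876 were higher and 3929 lower at 4 dpa, and 4141 differed by at least 2-fold.

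Among the genes with the largest increases, scpp6 had 835 counts at 4 dpa against 1 count at 0 dpa over the libraries of each group (471-fold, 95% counting interval 84.3 to 18630). The receptor gene gfra3 had 1016 against 2 counts (287-fold, 79.1 to 2370). Matrix protein genes scpp7 (log2 fold change 8.09, SE 0.272, edgeR adjusted p = 2.13e-07), scpp5 (7.30) and cmn (6.46) rose strongly as well. The log2 fold changes of and2 and and1 were 7.57 and 6.99 (edgeR adjusted p = 1.88e-07 and 2.13e-07), and reads of this similar pair may be split between them. The largest decreases were those of pck1, a gluconeogenesis enzyme (0.0693 ± 0.0218 against 10.2 ± 1.74 CPM, log2 -7.22), and of prg4a, which encodes a lubricating matrix protein (15.9 ± 8.29 against 918 ± 114 CPM, log2 -5.97). The transcription factor genes klf4 (-5.16), fosb (-4.69) and klf9 (-4.68) and the chemokine gene ccl19b (-4.99) followed.

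All 18 measured genes of the blastema list rose (median 2.39, camera adjusted p = 3.80e-19, adjusted p = 0.22 with an estimated correlation). They included fgf20a, a signal needed to start a blastema (log2 fold change 1.65, SE 0.274, edgeR adjusted p = 0.000572), the retinoic acid synthesis gene aldh1a2 (2.66), the homeobox gene msxb (1.71; current symbol msx1b) and fn1b (2.56). Proliferation genes moved as a block, with 45 of 46 cell cycle genes higher and 1 not called (median 2.27, camera adjusted p = 2.47e-33, adjusted p = 0.326 with an estimated correlation). Examples were mki67 (258 against 24.9 CPM, log2 3.27), ccnb1 (4.12), cdc20 (4.22) and ube2c (3.94). Of 38 extracellular matrix genes 36 rose and 1 fell (median 2.45, camera adjusted p = 3.41e-26, adjusted p = 0.326 with an estimated correlation). Among the higher ones were tnc, fbn2b (5.46) and mfap2 (3.90), and the one that fell was col17a1a of the epidermal basement membrane (-3.01). Among 16 osteoblast genes 12 rose and 2 fell (median 1.60, camera adjusted p = 1.70e-06, adjusted p = 0.292 with an estimated correlation). The bone genes col10a1a (14250.0 ± 1325 against 393 ± 73.8 CPM, log2 5.07), ifitm5 (3.75), sp7 (2.71) and phex (2.53) rose, and bglap, a marker of mature osteoblasts, fell (-1.22). Here col17a1a and bglap were picked after their values were seen. Fibroblast genes were mostly higher, with 11 of 17 up and 4 down (median 1.3, camera adjusted p = 0.000403, adjusted p = 0.292 with an estimated correlation). They included tph1b (46.1 against 1.85 CPM, log2 4.54), ogn (3.38) and prrx1b (2.75).

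Signalling genes moved in part. In the Wnt list 15 of 23 genes rose and 5 fell (median 0.58, camera adjusted p = 0.0194, adjusted p = 0.487 with an estimated correlation). Higher members were dkk3b (3.40), lef1 (3.38) and tcf7 (3.18). The Fgf list split into 9 higher and 5 lower of 19 (median 0.17, camera adjusted p = 0.499). Of its genes fgf3 (3.42) and etv4 (1.42) rose and dusp6, a feedback inhibitor of the pathway, fell (-1.31). Hedgehog and Bmp genes were 7 higher and 7 lower of 23 (median 0.14, camera adjusted p = 0.406). Within that list the Hedgehog ligand gene shha rose from 0.904 ± 0.00653 to 13 ± 0.777 CPM (log2 3.73), as did gli2a (1.75). Retinoic acid genes were divided (7 higher, 8 lower of 19; median -0.20, camera adjusted p = 0.896), with crabp2b up (2.28) and rbp4 down (-3.36). For joint and patterning genes the counts were 8 higher and 2 lower of 15 (median 0.35, camera adjusted p = 0.217). Their members dlx5a (1.59), hoxa13a (1.18) and hoxc13b (1.18) rose, and evx1, a gene of ray joints, was not called (0.06, edgeR adjusted p = 0.735). The early wound list gave 8 higher and 12 lower of 25 (median -0.39, camera adjusted p = 0.728). There hmox1a (2.34), mmp14b (2.98), mmp9 (1.18) and mmp13a (0.88) rose, jun (-1.34) and fosl1a (-2.51) fell, and il1b was not called (0.15, edgeR adjusted p = 0.511).

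Markers of other cell types shifted too. Epidermal genes fell, 31 of 40 being lower and 1 higher (median -1.26, camera adjusted p = 3.33e-07, adjusted p = 0.292 with an estimated correlation). The drop was largest among those named for krtt1c19e (-3.71), followed by evpla (-1.98), while the higher one was krt18 (2.35); keratin genes are similar in sequence and their reads may be split. Nerve and glial genes were lower in 12 of 19 and higher in 3 cases (median -1.13, camera adjusted p = 0.0194, adjusted p = 0.524 with an estimated correlation). The myelin genes plp1b (-4.22) and mbpb (-1.28) and their regulator egr2b (-3.54) were among those that fell. Pigment cell genes fell in 10 of 19 cases and rose in 1 (median -0.61, camera adjusted p = 0.0444, adjusted p = 0.852 with an estimated correlation; mlpha -2.53, kita -1.95, trpm1b -1.93). Endothelial genes rose in 15 of 21 cases and fell in 2 (median 1.1, camera adjusted p = 0.0187, adjusted p = 0.832 with an estimated correlation; stab1 2.17, flt4 1.76, fli1a 1.54). Dissociation and heat stress genes were lower in 18 of 27 cases and higher in 3 (median -1.26, camera adjusted p = 0.00182, adjusted p = 0.845 with an estimated correlation). In this list klf2a fell (-4.57) and hspa4a rose (1.75).

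The other lists were not called as sets. Leukocyte genes were 9 higher and 19 lower of 37 (median -0.53, camera adjusted p = 0.0596; lyz -3.89, il7r -2.59, lck -1.79). Interferon response genes were 5 higher and 12 lower of 32 (median -0.31, camera adjusted p = 0.358; stat1a -1.22, trim25 -0.91, abcb3l1 -1.18, current symbol tap2a). Glycolysis and hypoxia genes were 8 higher and 11 lower of 32 (median -0.10, camera adjusted p = 0.955), with pgam1a up (1.48) and bnip3 down (-2.31). Osteoclast genes gave 4 higher and 4 lower of 10 (median 0.35, camera adjusted p = 0.728), with ctsk (1.47) and acp5a (2.74) up and mitfa down (-1.12). Erythrocyte genes gave 2 higher and 1 lower of 14 (median -0.20, camera adjusted p = 0.963, the camera direction being up although the median lay below 0), with blf (3.42) and urod (1.22) up and hbaa1 (-1.22) down. Muscle genes gave 2 higher and 2 lower of 11 (median 0.00, camera adjusted p = 0.942), with tnnt3b up (2.74) and mb (-1.28) and mylz3 (-1.42) down. Adjusted over the list alone, the counts were the same except for cell cycle (46 higher), epidermis (2 higher), leukocyte (20 lower), endothelium (16 higher, 4 lower), glycolysis and hypoxia (7 higher, 10 lower) and interferon response (11 lower).

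Scaling by library size alone took the median of all genes from -0.01 to 0.44 (log2) and the split to 5699 higher and 2145 lower calls (72.7% against 49.7% higher), so directions here are relative to the TMM scaling; small changes weigh most in this, such as those of mmp13a (1.33 with that scaling), mitfa (-0.66), trim25 (-0.46) and the pigment list (median -0.15). Single libraries ended the calls of klf4 (either 4 dpa library; adjusted p 1.73e-14 to 0.0711 over the alternatives), acp5a (either 0 dpa library; 7.46e-15 to 0.0926) and the pigment list (replicate 2 of either group, median -0.31 without that of 4 dpa; 0.0106 to 0.175). The call of the pigment list also ended with DESeq2 (camera adjusted p = 0.0501) and in 1 fit of all replicated groups (0.175). DESeq2 ended the call of the nerve list (camera adjusted p = 0.0549). The fit of all replicated groups ended those of the endothelium list (camera adjusted p = 0.0804), mmp13a (edgeR adjusted p = 0.064) and mitfa (0.054).

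**Figure D1:**
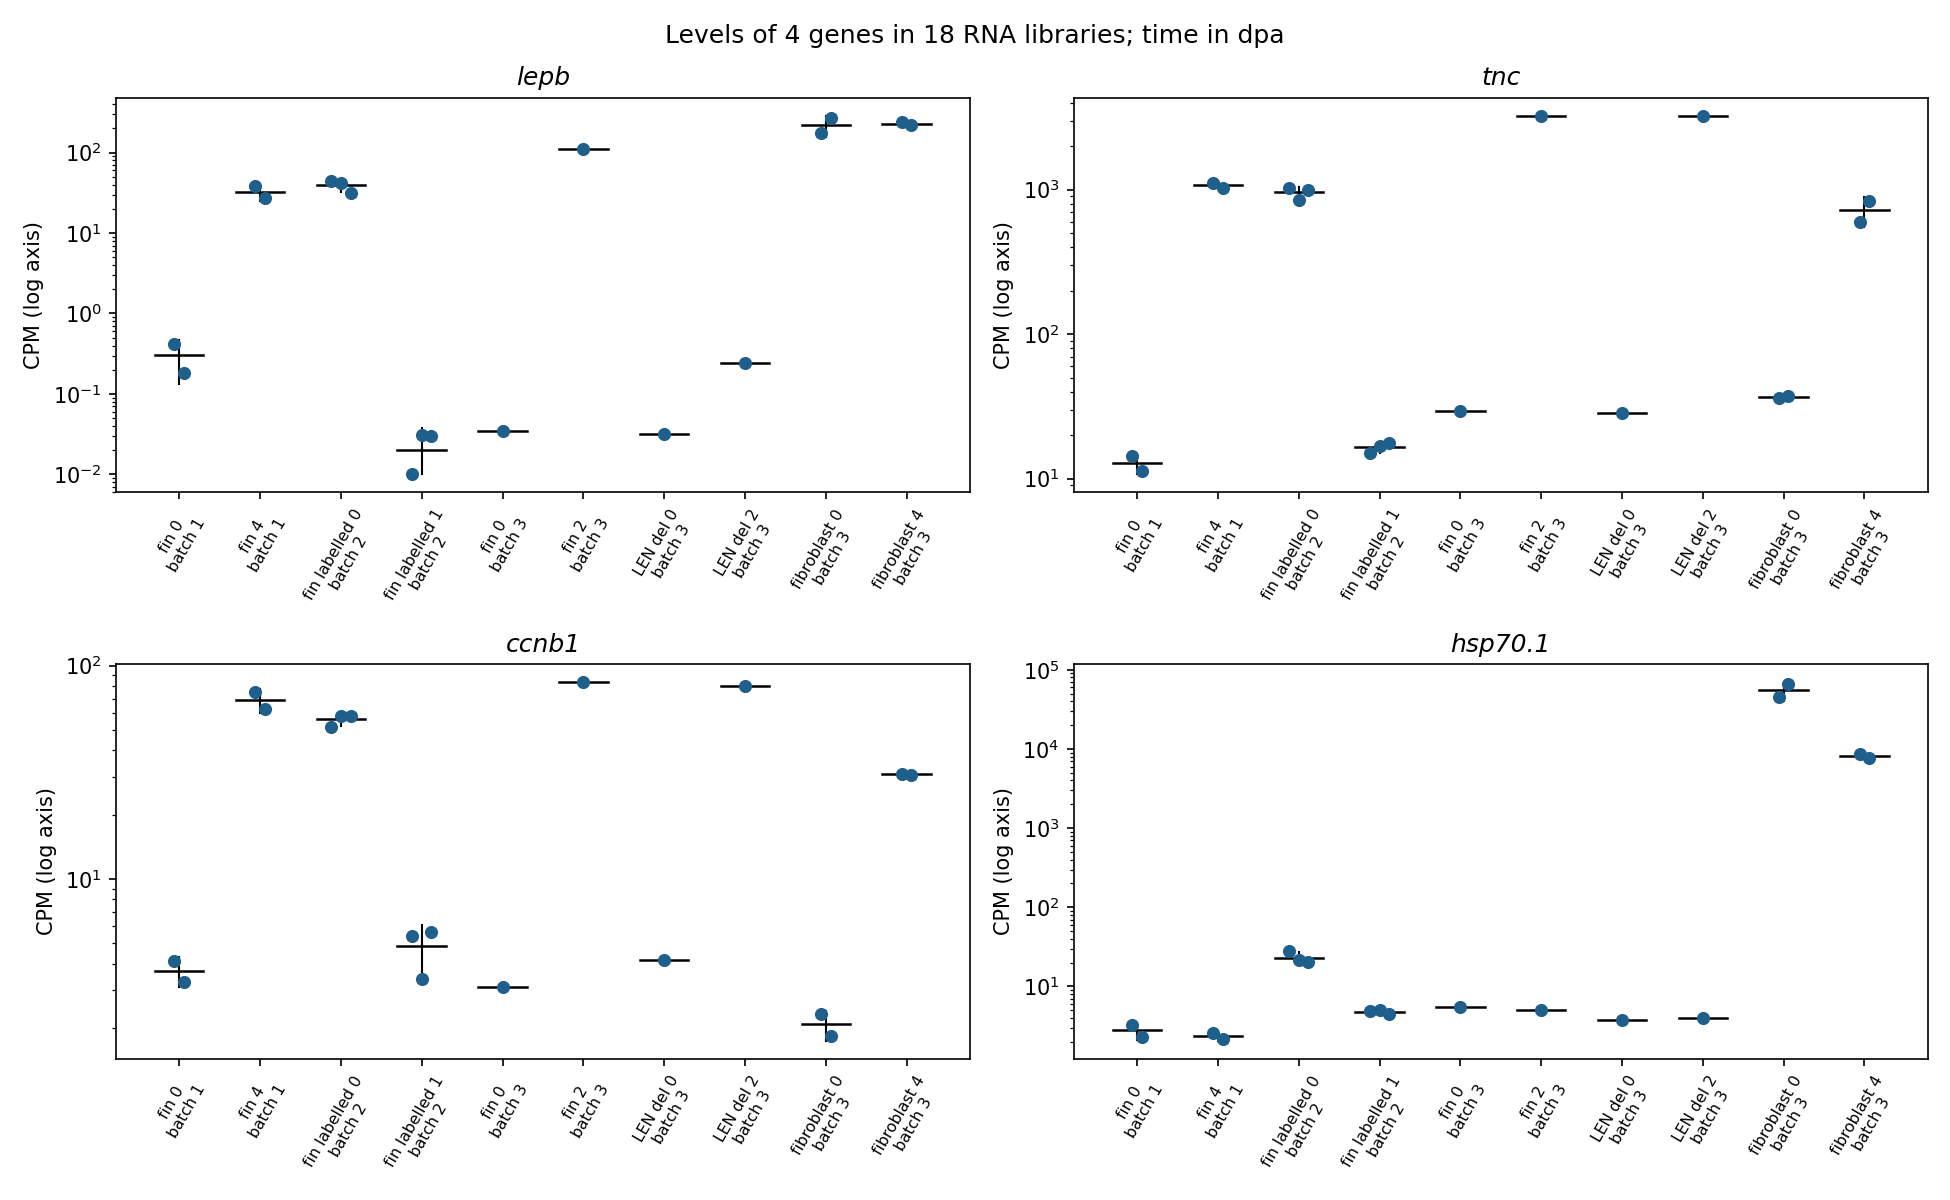
CPM (log axis) of lepb, tnc and ccnb1, chosen in advance, and of hsp70.1, picked after the values were seen, with each point 1 library. Bars are the group mean and lines the SD, and values under 0.01 are drawn at 0.01. The gene lepb lies near 0 in uninjured whole fins of batches 1 and 3 and in the libraries labelled 1 dpa of batch 2. It lies high in wild-type fins at 2 and 4 dpa, in the libraries labelled 0 dpa of batch 2 and in both fibroblast groups.

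The comparison of the libraries labelled 1 dpa with those labelled 0 dpa in batch 2 was designed to show the early injury response. Genes that rose in the 4 dpa fins of batch 1 were mostly higher in the libraries labelled 0 dpa. The leptin gene lepb had 3872 counts over the 3 libraries labelled 0 dpa (39.1 ± 6.87 CPM) and 2 counts over the 3 labelled 1 dpa (0.0201 ± 0.0175 CPM), a 1898-fold lower level (95% counting interval 525 to 15677). The blastema gene tnc stood at 958 ± 90.6 CPM in the libraries labelled 0 dpa and 16.4 ± 1.32 CPM in those labelled 1 dpa (log2 fold change -5.80, SE 0.101, edgeR adjusted p = 9.62e-10). Fibronectin gene fn1b (32486 and 403 CPM; -6.27) and nearly all cell cycle genes differed the same way. Higher in the libraries labelled 1 dpa were 27 of 37 leukocyte, 16 of 19 pigment and 12 of 18 nerve and glial genes. No list of batch 2 kept its call with an estimated correlation, a test that rests on few residual degrees of freedom. In edgeR's test 9711 of 11851 genes differed, 4981 higher and 4730 lower in the libraries labelled 1 dpa, with 5022 changed by at least 2-fold.

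Across 11598 genes tested in both batches, the log2 fold changes of batch 2 (labelled 1 minus 0 dpa) and of batch 1 (4 minus 0 dpa) had a Pearson r of -0.644 (Spearman -0.662), a description across genes, which are not independent replicates. Of these genes, 2786 were higher at 4 dpa in batch 1 and lower in the libraries labelled 1 dpa, where independent lists would share 1498, and 3045 were lower and higher, where independent lists would share 1627. In the same direction 506 were higher and 282 lower in both. Each of the 6 libraries of batch 2 had its highest Spearman correlation with a whole-fin library of the other class, injured or not. Those labelled 0 dpa were closest to the wild-type fin at 2 dpa of batch 3 (0.948 to 0.954) and those labelled 1 dpa to uninjured fins (0.963 to 0.967).

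The macrophage gene mpeg1.3 was the gene most raised in the libraries labelled 1 dpa (184 ± 21.1 against 0.503 ± 0.0312 CPM; log2 fold change 8.57, SE 0.126, edgeR adjusted p = 6.49e-10). It was followed by snai3 (8.23), oxgr1a.1 (7.33), the epithelial transcription factor gene foxn1 (7.18) and the myostatin gene mstnb (7.16). Next came irg1l (6.90), the keratin gene krtt1c19e (6.88) and the chemokine gene ccl27b (582 against 5.54 CPM, 6.78). Members of the mpeg1, keratin and chemokine families have near copies, so their counts are uncertain. Lower were lepb, cdh17 (2 against 1764 counts, 865-fold, 239 to 7145), the coagulation factor gene f5 (-9.80), cmn (-9.21), the mechanosensory channel gene trpn1 (-9.21) and krt93 (9.33 against 3374 CPM, log2 -8.44).

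Of 16 blastema genes 11 were lower and 5 higher in the libraries labelled 1 dpa (median -2.36, camera adjusted p = 1.18e-05, adjusted p = 0.14 with an estimated correlation). Lower ones were fgf20a (-5.79), aldh1a2 (-2.12) and mdka (-3.59), while msxb was higher (0.29). Of 46 cell cycle genes 45 were lower and 1 was not called (median -2.64, camera adjusted p = 5.83e-14, adjusted p = 0.701 with an estimated correlation; mki67 -2.64, ccnb1 -3.47, chaf1b -2.69). In the extracellular matrix list 10 were higher and 19 lower of 38 (median -0.35, camera adjusted p = 0.0499, adjusted p = 0.701 with an estimated correlation). There fn1a (-4.83) and fbn2b (-4.47) were lower and lum (3.42) higher, as was mmp2 of the fibroblast list (1.94). Osteoblast genes were higher in 11 and lower in 1 of 16 cases (median 1.07, camera adjusted p = 0.0028, adjusted p = 0.323 with an estimated correlation; bglap 4.22, ifitm5 3.77, alpl 2.55, sp7 2.06). Leukocyte genes were higher in 27 and lower in 4 of 37 (median 1.12, camera adjusted p = 0.000592, adjusted p = 0.701 with an estimated correlation; mpeg1.2 3.38, il7r 3.87). Pigment genes were higher in 16 of 19 cases, the others not being called (median 1.77, camera adjusted p = 0.00599, adjusted p = 0.701 with an estimated correlation; kita 2.1, ltk 2.27). Nerve and glial genes were higher in 12 and lower in 3 of 18 (median 1.33, camera adjusted p = 0.0117, adjusted p = 0.353 with an estimated correlation), among them plp1b (6.44) and pmp22a (2.75). Glycolysis and hypoxia genes were lower in 23 and higher in 5 of 34 (median -0.69, camera adjusted p = 0.0338, adjusted p = 0.701 with an estimated correlation). Of these pgam1a (-2.33) and pgk1 (-1.27) were lower and bnip3 higher (4.13).

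The remaining lists of batch 2 were not called as sets. Early wound genes were 6 higher and 10 lower of 24 (median -0.03, camera adjusted p = 0.529). Lower were timp2b (-5.51), mmp13a (-4.36), fosl2 (-2.98), socs3b (-0.85), mmp9 (-0.88) and fosl1a (-1.77), and il1b was not called (-0.50, edgeR adjusted p = 0.245). Wnt genes gave 11 higher and 8 lower of 23 (median 0.31, camera adjusted p = 0.904; wif1 2.49, lef1 -3.24). Fgf genes gave 8 and 7 of 18 in that order (median 0.14, camera adjusted p = 0.602; fgfr4 3.43, etv4 -2.52). Hedgehog and Bmp genes gave 16 and 6 of 25 (median 0.67, camera adjusted p = 0.255; shha -3.89, id3 1.63, gli2a -1.90). For retinoic acid genes the counts were 10 and 3 of 18 (median 0.51, camera adjusted p = 0.481; rbp4 4.57, crabp2b -3.58). Joint and patterning genes gave 10 and 2 of 15 (median 0.50, camera adjusted p = 0.166; evx1 1.53, pax9 1.60). Fibroblast genes gave 9 and 6 of 17 (median 0.51, camera adjusted p = 0.529; tph1b -5.59, lum 3.42). Epidermal genes gave 16 and 14 of 40 (median 0.07, camera adjusted p = 0.529; krtt1c19e 6.88, krt94 -6.97, krt18 -6.96).

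Endothelial genes of batch 2 gave 11 higher and 5 lower of 20 (median 0.35, camera adjusted p = 0.166; vwf 4.02). Erythrocyte genes gave 4 and 6 of 14 (median -0.35, camera adjusted p = 0.798; rhag 3.92) and muscle genes 5 and 2 of 9 (median 1.94, camera adjusted p = 0.529; mb 2.43, tnnt3b -3.42). Osteoclast genes gave 3 and 5 of 10 (median -0.12, camera adjusted p = 0.982; acp5b 2.29). For stress genes the counts were 13 and 8 of 26 (median 0.56, camera adjusted p = 0.904; bag3 1.62, hsp70.1 -2.21). Interferon genes gave 21 and 6 of 32 (median 0.46, camera adjusted p = 0.166; stat1a 1.18, parp12b 1.04). Adjusted over the list alone, the counts were the same for the lists called as sets except glycolysis and hypoxia (6 higher).

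Several alternatives ended the call of the matrix list (0.00375 to 0.24), among them the replicate number as a block (adjusted p = 0.052) and leaving out replicate 2 labelled 0 dpa (0.237) or replicate 1 labelled 1 dpa (0.131), and limma-voom ended that of the blastema list (1.04e-08 to 0.0774). Calls were also lost for fosl1a (0.00271 to 0.107; without replicate 2 labelled 0 dpa or any labelled 1 dpa, and -1.13 without replicate 1 labelled 0 dpa), mmp9 (0.000243 to 0.056; without replicate 3 labelled 1 dpa) and msxb (0.000615 to 0.0977; in the fit of all groups, and 0.19 without replicate 1 labelled 0 dpa).

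**Figure D2:**
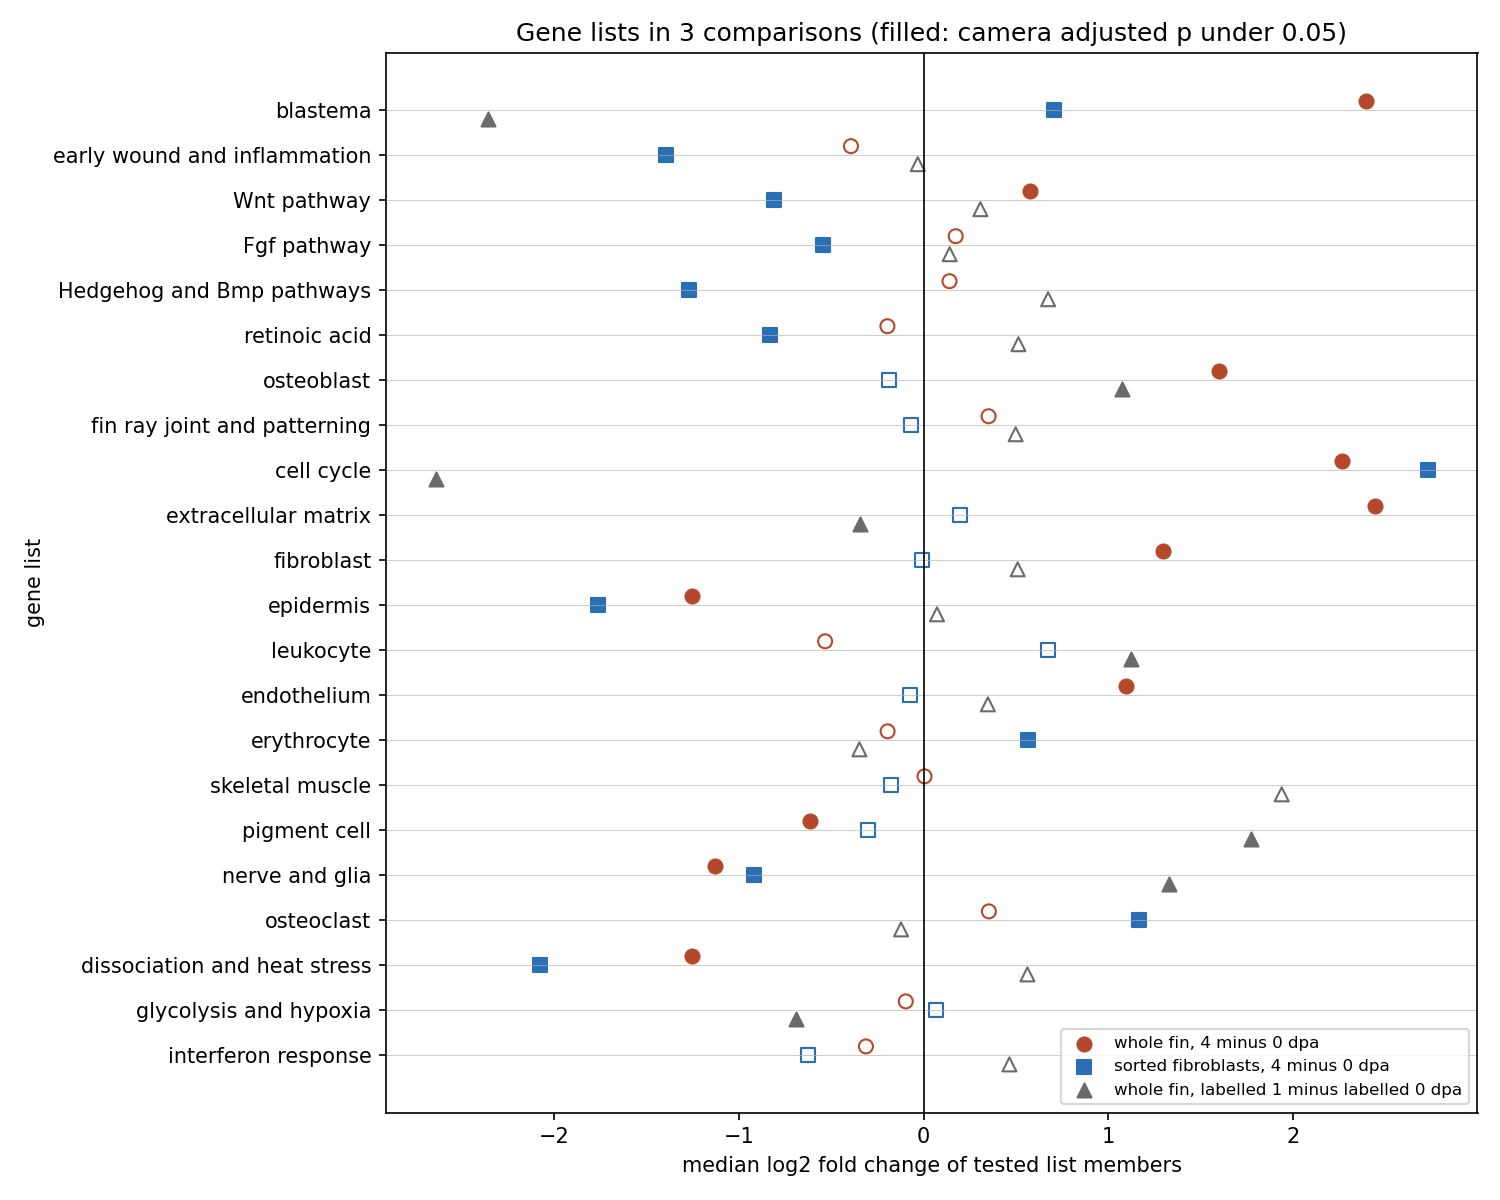
Median log2 fold change (axis) of each gene list fixed in advance, as circles for whole fins at 4 against 0 dpa, squares for sorted fibroblasts at 4 against 0 dpa and triangles for libraries labelled 1 against 0 dpa; filled symbols have a camera adjusted p under 0.05. The cell cycle list lies at 2.27 and 2.73 in the 4 dpa comparisons and at -2.64 in batch 2.

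Sorted fibroblasts at 4 dpa were compared with sorted fibroblasts of uninjured fins to follow this lineage during outgrowth. Fibroblasts from regenerating fins had much more and2 (7948 ± 1224 against 5.09 ± 2.44 CPM, n = 2 each; log2 fold change 10.71, SE 0.447, edgeR adjusted p = 2.64e-06) and cell cycle transcript. Their own marker gene tph1b rose from 6.14 ± 0.614 to 203 ± 0.138 CPM (log2 fold change 5.14, SE 0.173, edgeR adjusted p = 5.22e-07). The gene lepb, which rose in whole fins, was already at 222 ± 64.3 CPM in fibroblasts of uninjured fins and stood at 229 ± 15.2 CPM at 4 dpa (log2 fold change 0.15, edgeR adjusted p = 0.581, not called). Lower at 4 dpa than in the fibroblasts of uninjured fins were 22 of 27 stress genes, 25 of 38 epidermal genes and 15 of 23 Hedgehog and Bmp genes. No list of this comparison kept its call with an estimated correlation, a test that rests on few residual degrees of freedom. In all, 6477 of 12011 genes differed by edgeR, 3335 higher and 3142 lower at 4 dpa, with 4089 changed by at least 2-fold.

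The largest increases besides and2 were those of and1 (21498 ± 3562 against 153 ± 49.0 CPM, log2 7.23), g2e3 (5.78), the laminin gene lama1 (5.66), pcp4a (1023 against 23.8 CPM, log2 5.52), the mitotic checkpoint gene mad2l1 (5.36) and lrrn1 (5.03). The largest decreases were those of pck1 (0.869 against 129 CPM, log2 -7.11), the ion channel gene asic1a (-6.92), prg4a (19.3 against 2415 CPM, log2 -6.87), spon1a (-6.26), neu3.4 (-5.72) and gpm6ab (-5.47). Cell cycle genes were higher in 41 of 46 cases and not called in 5 (median 2.73, camera adjusted p = 2.06e-23, adjusted p = 0.386 with an estimated correlation; mki67 3.85, ccnb1 3.99, top2a 3.82). Of 17 blastema genes 9 rose and 4 fell (median 0.70, camera adjusted p = 0.000247, adjusted p = 0.386 with an estimated correlation). The matrix gene tnc rose from 37.0 ± 0.765 to 719 ± 169 CPM (4.37), and msxb (-0.73) and fn1b (-0.89) fell. The genes aldh1a2 (0.34, edgeR adjusted p = 0.0719) and sp7 (0.13, edgeR adjusted p = 0.885) were not called. In simulated data the fibroblast test recovered 0% of changes of 0.5 and 46.2% of changes of 1 (log2), so small changes can be missed. Both fgf20a and shha were too low to be tested here, shha having 3 counts at 4 dpa and 9 at 0 dpa.

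Several groups were lower at 4 dpa. In the dissociation and heat stress list 22 of 27 genes fell and 5 were not called (median -2.08, camera adjusted p = 1.18e-14, adjusted p = 0.386 with an estimated correlation). Those that fell included jun (-2.58), fosab (-3.36) and bag3 (-2.39). The heat shock gene hsp70.1 stood at 8083 ± 632 CPM at 4 dpa and 55106 ± 14674 CPM in fibroblasts of uninjured fins. Early wound genes moved with these stress genes, several of which both lists hold, 18 of 28 falling and 7 rising (median -1.39, camera adjusted p = 0.000221, adjusted p = 0.386 with an estimated correlation). Among them ptgs2a (-2.49) and fosl1a (146 against 1132 CPM, log2 -2.85) fell, and il1b (57.3 ± 27.0 against 9.53 ± 5.33 CPM; log2 fold change 2.70, SE 0.579, edgeR adjusted p = 0.0178) and mmp13a (2.35) rose. Epidermal genes fell in 25 of 38 cases and rose in 2 (median -1.76, camera adjusted p = 0.000144, adjusted p = 0.644 with an estimated correlation; krt4 -1.78, krt15 -2.68, ppl -2.33). The keratin gene krt5, picked with hsp70.1 for its abundance after the values were seen, stood at 18582 ± 12794 CPM at 0 dpa and 3023 ± 5.66 CPM at 4 dpa. Hedgehog and Bmp genes fell in 15 of 23 cases and rose in 2 (median -1.27, camera adjusted p = 0.000611, adjusted p = 0.386 with an estimated correlation; hhip -2.89, bmp7b -1.83, bmp4 -1.38). Retinoic acid genes fell in 10 of 18 and rose in 2 (median -0.83, camera adjusted p = 0.000247, adjusted p = 0.386 with an estimated correlation; rbp4 -4.13, crabp1b -3.04, cyp26b1 -2.42). Wnt genes fell in 13 of 23 and rose in 4 (median -0.81, camera adjusted p = 0.0118, adjusted p = 0.386 with an estimated correlation). Of these the inhibitor genes wif1 (-4.79) and notum1a (-3.87) fell and dkk3b rose (3.36). Fgf genes fell in 9 of 17 and rose in 2 (median -0.55, camera adjusted p = 0.0387, adjusted p = 0.644 with an estimated correlation; fgf24 -2.43, fgfr3 -2.29). Nerve and glial genes fell in 11 of 18 and were not called in 7 (median -0.92, camera adjusted p = 0.0158, adjusted p = 0.386 with an estimated correlation; gfap -2.87, pmp22b -1.73).

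Osteoclast genes rose in 7 of 10 cases and fell in 1 (median 1.17, camera adjusted p = 0.0325, adjusted p = 0.386 with an estimated correlation; ocstamp 2.00, ctsk 1.95). Erythrocyte genes rose in 8 of 16 and fell in 1 (median 0.57, camera adjusted p = 0.041, adjusted p = 0.386 with an estimated correlation). They included hbaa1 (4.26), whose reads may be shared with its near copies, and alas2 (2.32). Osteoclast and erythrocyte genes mark other cell types, and whether such cells or their RNA were in the sorted samples was not tested. Lists not called as sets were those of the extracellular matrix (16 higher and 7 lower of 38; median 0.20, camera adjusted p = 0.0544; fbn2b 2.41, p4ha1b 2.14) and of fibroblasts (4 and 5 of 17 in that order; median -0.01, camera adjusted p = 0.969; cxcl12a -2.49, thy1 -1.75). Leukocyte genes gave 19 and 7 of 37 (median 0.67, camera adjusted p = 0.0754; csf1ra 1.42, rac2 1.34), with a median of 1.26 and a call without replicate 2 of the 0 dpa fibroblasts. Interferon genes gave 3 and 13 of 31 (median -0.63, camera adjusted p = 0.0544; stat1b -1.35). Among osteoblast genes 3 were higher and 6 lower of 16 (median -0.19, camera adjusted p = 0.195; bglap -3.69, spp1 -2.94). Joint and patterning genes gave 1 and 6 of 15 (median -0.07, camera adjusted p = 0.126; prg4b -4.43, evx1 -0.99). Endothelial genes gave 3 and 5 of 20 (median -0.07, camera adjusted p = 0.784; sox7 -1.69) and pigment genes 3 and 4 of 19 (median -0.30, camera adjusted p = 0.759; ltk -2.43). Muscle genes gave 3 and 3 of 15 (median -0.18, camera adjusted p = 0.763; mb -2.87, ckma 1.75). Glycolysis and hypoxia genes gave 8 and 8 of 35 (median 0.07, camera adjusted p = 0.759; ankrd37 3.54, aldocb -1.52). Adjusted over the list alone, the counts of the lists called as sets were the same except for Wnt (15 lower).

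Of 11496 genes tested in both tissues, 2113 rose and 1846 fell in both whole fins and fibroblasts at 4 dpa, where independent lists would share 1089 and 981. A further 411 and 303 moved in opposite directions. Without replicate 1 or 2 of the 4 dpa fibroblasts 3827 and 4026 genes were called, and each of those alternatives, as well as library-size scaling (msxb -0.40, fn1b -0.58, mmp9 -0.24), ended the calls of msxb (2.03e-07 to 0.126), fn1b (2.94e-12 to 0.0938) and mmp9 (log2 -0.56; adjusted p 4.63e-05 to 0.322); without replicate 2 of the 0 dpa fibroblasts lepb was called (0.46; adjusted p 0.0149 to 0.905 over the alternatives). Library-size scaling took the all-gene median from near 0 to 0.32 and the higher share from 51.5 to 67.7%. Leaving out replicate 1 of 0 dpa ended the call of the blastema list (median 0.70). Several alternatives ended that of the Fgf list, among them library-size scaling (median -0.23, camera adjusted p = 0.0538). The erythrocyte list lost its call with that scaling (0.0847), DESeq2 (0.0683, median 0.23), limma-voom (0.0843) and other alternatives. In 1 fit of all replicated groups the Fgf (camera adjusted p = 0.0503), erythrocyte (0.143), early wound (0.0651) and osteoclast lists (0.0917) were not called.

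The difference between the fibroblast and whole-fin responses at 4 dpa was tested as an interaction of the 4 groups. The fibroblast response was the more negative one for most blastema, matrix, bone and Wnt genes and the more positive one for 17 of 37 leukocyte genes. None of these lists kept its call with an estimated correlation, a test that rests on few residual degrees of freedom. The gene lepb differed most among the genes chosen in advance (log2 difference -6.48, SE 0.473, edgeR adjusted p = 2.74e-05). In total 4511 of 12442 genes differed, 2345 with a more positive and 2166 with a more negative response in fibroblasts, and 3109 by at least 2-fold. The largest positive differences were those of hbaa1 (5.51), epdl1 (5.31), the arginase gene arg2 (4.85), rgs2 (4.62) and grn2 (4.45). The largest negative ones were those of the basement membrane genes frem2a (-6.89) and frem3 (-6.70), the histamine receptor gene hrh3 (-6.64), lepb and spon1a (-5.30). Genes chosen in advance with a more negative response were shha (-5.33, resting on 3 counts at 4 dpa and 9 at 0 dpa in fibroblasts), fn1b (-3.41), sp7 (-2.55), msxb (-2.41), aldh1a2 (-2.28), tnc (-1.87), mmp9 (-1.70) and evx1 (-1.01). In fibroblasts sp7 had only 7 to 18 counts per library, and fgf20a, given below, 1 to 8.

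By list, the fibroblast response was the more negative one for 34 of 38 matrix genes (median -1.87, camera adjusted p = 5.04e-26, adjusted p = 0.0759 with an estimated correlation). So it was for 13 of 16 osteoblast genes (median -1.44, camera adjusted p = 8.69e-12, adjusted p = 0.0758 with an estimated correlation) and 17 of 23 Wnt genes (median -2.08, camera adjusted p = 1.74e-09, adjusted p = 0.0709 with an estimated correlation). Hedgehog and Bmp genes (16 of 24; median -1.02, camera adjusted p = 5.16e-06, adjusted p = 0.111 with an estimated correlation) and blastema genes (12 of 18; median -1.96, camera adjusted p = 4.84e-06, adjusted p = 0.232 with an estimated correlation) showed the same direction. Fibroblast genes (12 of 17; median -1.40, camera adjusted p = 1.73e-05, adjusted p = 0.0759 with an estimated correlation) and retinoic acid genes (13 of 19; median -1.29, camera adjusted p = 9.14e-05, adjusted p = 0.0927 with an estimated correlation) did so as well. The more negative response also held for 11 of 19 Fgf genes (median -0.75, camera adjusted p = 0.00189, adjusted p = 0.465 with an estimated correlation) and 8 of 15 joint genes (median -0.78, camera adjusted p = 0.00197, adjusted p = 0.465 with an estimated correlation). Endothelial genes had a more negative response in 7 of 21 cases (median -0.83, camera adjusted p = 0.0324, adjusted p = 0.641 with an estimated correlation). A more positive response was found for 17 of 37 leukocyte genes (median 1.07, camera adjusted p = 4.15e-05, adjusted p = 0.484 with an estimated correlation) and 7 of 16 erythrocyte genes (median 0.57, camera adjusted p = 0.0353, adjusted p = 0.465 with an estimated correlation). Both lists mark blood cells, and whether such cells or their RNA were in the sorted samples was not tested. Not called were the early wound, cell cycle, epidermis, muscle, pigment, nerve, osteoclast, stress, glycolysis and interferon lists (camera adjusted p from 0.0603 to 0.784). For stress genes the median (0.08) and the camera direction (down) differed in sign. Adjusted over the list alone, the counts named were the same except for matrix (35), Hedgehog and Bmp (17), Fgf (12) and leukocyte (21).

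Tissue and batch cannot be told apart in this difference, and the more positive share of 52.0% became 38.9% with library-size scaling (all-gene median -0.11), 36.9% in 1 fit of all replicated groups (-0.18), 38.8% without replicate 2 of the 0 dpa fins and 41.8 and 39.5% without replicate 1 or 2 of the 0 dpa fibroblasts. Without replicate 1 of the 4 dpa fins 2971 genes were called, and the differences of fgf20a (-2.84; adjusted p 0.00281 to 0.0848 over the alternatives), il1b (2.59; 1.88e-05 to 0.0935, with 0.0798 under the replicate block) and mmp13a (1.5; 0.000419 to 0.101) lost their calls without any of several single libraries.

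The responses of batch 1 (4 minus 0 dpa) and batch 2 (labelled 1 minus labelled 0 dpa) were also set against each other, to separate early from later changes. As labelled, they ran in opposite directions for many blastema, matrix and cell cycle genes. The largest positive differences were those of lepb, by 17.39 (log2), cmn by 15.82, f5 by 14.48, adam8a by 12.94 and tnc by 12.23. The fitted value of lepb rests on 2 counts in the libraries labelled 1 dpa. Of 12277 genes 9939 differed by edgeR, 5156 with a more positive and 4783 with a more negative response in batch 1, and 7520 by at least 2-fold. The most negative differences were those of mpeg1.3 (-12.34), foxn1 (-10.98), snai3 (-10.71), plp1b (-10.52) and krtt1c19e (-10.44). These values rest on the labels of batch 2. With its groups exchanged, an alternative added after the levels of injury genes were seen, the log2 differences were -3.86 for lepb, -2.69 for cmn, -5.22 for f5, -2.05 for adam8a and 0.53 for tnc. In the same exchange mpeg1.3 (4.70), foxn1 (3.27), snai3 (5.64), plp1b (2.27) and krtt1c19e (3.22) turned positive. As labelled, blastema genes were more positive in 16 and more negative in 1 of 18 cases (median 4.97, camera adjusted p = 1.55e-10, 0.0148 with an estimated correlation). Cell cycle genes were more positive in 45 of 46 (5.09, 1.02e-22; adjusted p = 0.397 with an estimated correlation) and matrix genes in 33 of 38 (3.16, 1.46e-10; adjusted p = 0.367 with an estimated correlation). Leukocyte (22 of 37, -1.61, camera adjusted p = 0.000526), pigment (14 of 19, -2.10, 0.00803) and nerve genes (13 of 20, -2.18, 0.00736) were more negative, with adjusted p = 0.868, 0.868 and 0.367 under an estimated correlation. The early wound list, with 10 more positive and 10 more negative of 26, was not called (median -0.49, camera adjusted p = 0.927), nor were the other lists (from 0.0565 to 0.987). With the groups of batch 2 exchanged, 6381 genes differed, 3163 with a more positive and 3218 with a more negative response in batch 1; batch and time cannot be told apart here.

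Single whole-fin libraries of batch 3 addressed how deletion of LEN alters the response at 2 dpa. Counts per gene cannot check a deletion of noncoding DNA, so the genotypes rest on the labels. In the wild-type library lepb went from 1 count at 0 dpa to 3698 counts at 2 dpa (128.6 CPM in the scaling of these 4 libraries, 95% Poisson interval 124 to 133). The deletion libraries had 1 count at 0 dpa and 8 counts at 2 dpa (0.286 CPM, 0.123 to 0.563). The level at 2 dpa was thus 450-fold lower in the deletion library than in the wild-type library (228 to 1043). Its log2 ratio (-8.48) was the lowest of the 10372 genes with at least 50 counts in the higher library. Several blastema and growth genes were at similar levels in both libraries at 2 dpa, namely tnc (3749 CPM with and 3754 CPM without the deletion; log2 ratio 0.00), fgf20a (-0.08, -0.26 to 0.10), shha (-0.11), aldh1a2 (0.04), msxb (-0.01) and mki67 (0.02). Other genes chosen in advance were lower in the deletion, namely fosl1a (-1.19), il1b (-0.36), tph1b (-0.35) and mmp9 (-0.23), or higher, as mmp13a (0.41) and fn1b (0.16). For sp7 (-0.20, 205 counts in the deletion against 243) the counting interval included no change. The stress list lay below all matched random lists (median -0.30, 8 of 26 members more than 2-fold lower), and the early wound list, which shares genes with it, at percentile 0.04 (-0.10, 4 of 25). The blastema list, which includes lepb, lay slightly low as a whole (median -0.08, percentile 0.94), as did the Hedgehog and Bmp (-0.11, 0.36), fibroblast (-0.09, 0.59) and erythrocyte lists (-0.23, 0.76). With 1 library per genotype and time there is no replicate check and no p-value, the ratios compare these libraries, and the intervals and floors cover counting error only. Percentiles of lists take no account of members that vary together.

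Between 0 and 2 dpa the wild-type library gained lepb (3173-fold, 569 to 125353), cmn (log2 ratio 9.57), and2 (8.74), f5 (8.11) and ggt1a (3 against 970 counts, 277-fold, 94.6 to 1348). It lost pck1 (332 counts at 0 dpa and 0 at 2 dpa, at least 129-fold by a floor of 3 counts), cyb5r2 (-7.36), acss2l (-6.53), ccl27b (-6.49) and ptgdsb (-6.45). The deletion library gained cmn (9.57), f5 (8.79), and2 (8.46), ggt1a (1 against 632 counts, 609-fold, 109 to 24089) and tph1b (7.64). It lost mpeg1.3 (630 against 3 counts, 218-fold, 74.2 to 1060), igfn1.1 (309 against 1 count, 321-fold, 57.1 to 12707), ccl27b (-6.18), ptgdsb (-6.03) and pck1 (132 against 0 counts, at least 45.7-fold). Its lepb ratio was 7.71-fold (1.03 to 342). Of the genes chosen in advance, many had log2 ratios of similar size in wild type and deletion, in that order: fgf20a 5.45 and 5.77, tnc 6.77 and 6.79, fn1b 4.13 and 4.64, aldh1a2 3.11 and 3.36, shha 5.39 and 5.38, mki67 3.08 and 2.66, msxb 1.37 and 1.43, mmp9 1.32 and 1.33, tph1b 7.12 and 7.64, and ccnb1 4.72 and 4.24. Among these, the counting intervals of fn1b and mki67 did not overlap between the genotypes. Other genes lay further apart, also with intervals that did not overlap: il1b 1.61 (1.25 to 2.04) and 0.53 (0.21 to 0.87), mmp13a 0.75 (0.53 to 0.98) and 1.82 (1.59 to 2.08), sp7 1.18 (0.84 to 1.56) and 0.38 (0.08 to 0.70), and evx1 -1.67 (-1.88 to -1.48) and -1.05 (-1.26 to -0.85). For fosl1a the ratios were 1.96 and 1.41. For evx1 the gap lay at 0 dpa, at 27.0 CPM in wild type and 18.1 CPM in the deletion (scaling of all 18 libraries). At 2 dpa evx1 stood at 8.46 and 8.83 CPM. For il1b and sp7 the deletion was higher at 0 dpa and lower at 2 dpa, and for mmp13a the reverse. Replicate pools of other groups differed by more than counting error. Intervals that do not overlap therefore do not show a response that depends on genotype.

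More than 2-fold differences between 0 and 2 dpa were seen for 26.6% of genes in wild type and 28.9% in the deletion. Over 2888 genes with a wild-type change of at least 2-fold, the slope of the deletion response on the wild-type response was 0.929 and 99.5% had the same sign. Over all genes compared, the responses had a Pearson r of 0.940, a description across genes. Among gene lists, the blastema list had a median log2 ratio of 2.87 in wild type and 2.87 in the deletion, the cell cycle list 1.92 and 2.11 and the matrix list 1.53 and 1.5, each above the whole range of 10000 random lists matched on expression (percentile 100). Pigment genes lay low in both (-1.23 and -1.12, percentiles 0 and 0.04), as did leukocyte genes (-0.56 and -0.81, percentiles 0.01 and 0).

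After lepb, the largest decreases in the deletion library at 2 dpa were those of the immediate-early genes fosb (213 against 1649 counts, log2 ratio -2.90), nr4a1 (-2.74) and klf4 (-2.42) and of sox19a (-2.23). The AP-1 gene fosl1a was also lower (-1.19, -1.42 to -0.99). Higher in the deletion were ccl38a.4 (1.91), nitr1m (1.84), socs1b (1.63), ccl34a.3 (1.53) and ccl34a.4 (1.51), of which the chemokine genes have near copies. Of the genes within 200 kb of lepb in the GRCz12tu gene table, 5 had enough counts to compare, and their log2 ratios were 0.03 for cbll1, 0.19 for bik, -0.36 for mcat, 0.07 for rap1b and -0.23 for impdh1b; slc26a3.1 had 0 and 2 counts, and the other neighbours could not be compared. At 0 dpa the deletion library had more mpeg1.3 (630 against 56 counts, 3.32), lifra (2.70), gig2q (2.69), ccl19a.2 (2.55) and nkx2.2b (2.41) and less nansb (-1.78), sh2d3cb (-1.73), ugt5a1 (-1.71), znf1147 (-1.55) and loxl2a (-1.54). The spread of log2 ratios between genotypes was 0.373 (SD over 10477 genes) at 0 dpa and 0.265 (SD over 10372 genes) at 2 dpa, where 34 genes were more than 2-fold higher and 50 more than 2-fold lower in the deletion.

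**Figure D3:**
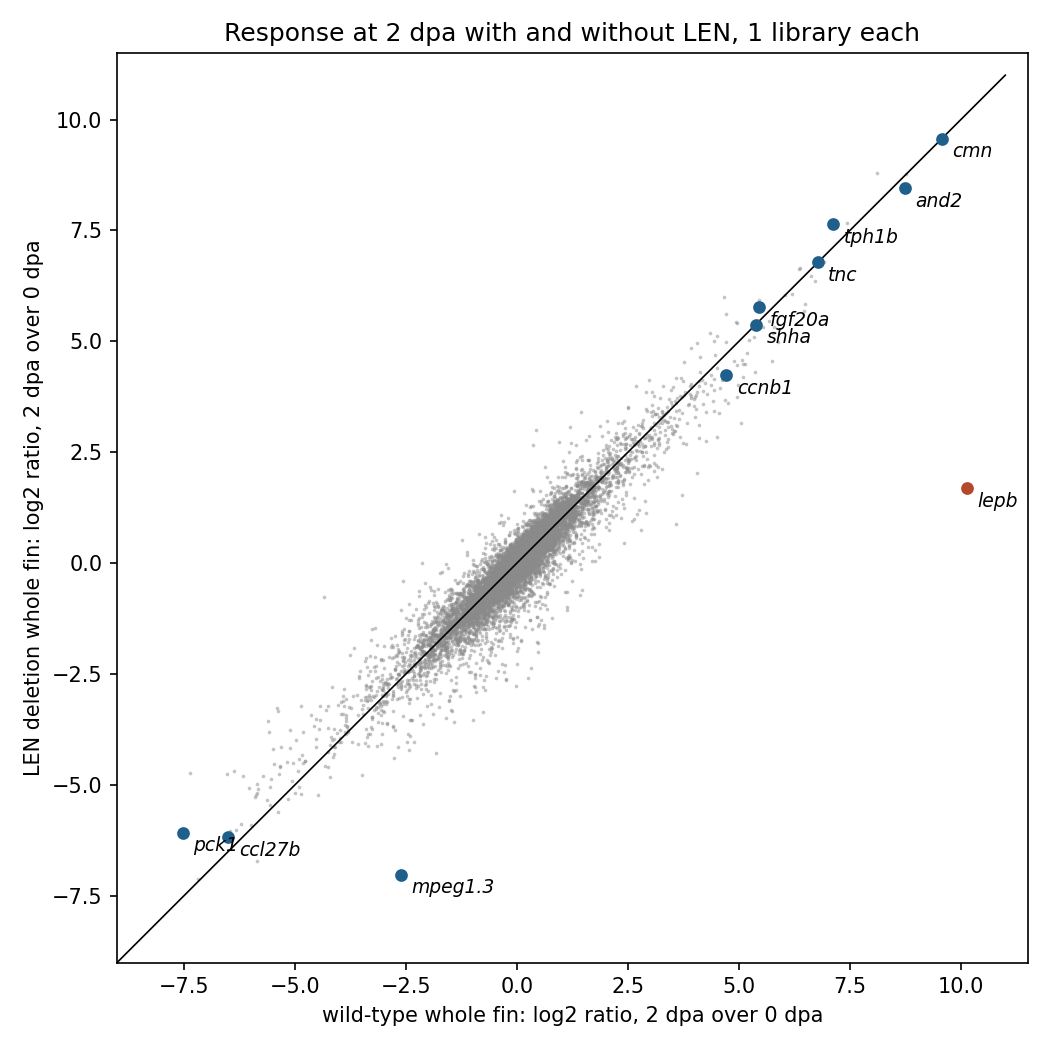
Log2 ratio of 2 over 0 dpa in the deletion libraries (vertical axis) against that in the wild-type libraries (horizontal axis), each point 1 gene. Most genes lie near the diagonal (slope 0.929), and lepb lies at 10.14 in wild type and 1.70 in the deletion.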

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

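Of the tests below, those of the nearest libraries, of the labels as given, of stress genes, of lepb enrichment and of the LEN deletion and the exchange of the batch 2 groups were chosen after the results were seen; those of the early wound list, the epidermis list and the splits were planned.

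Fibroblasts and whole fins differed in their 4 dpa response for 4511 genes by edgeR's interaction test. The log2 differences of the largest genes were 5.51 for hbaa1, 5.31 for epdl1, 4.85 for arg2, 4.62 for rgs2, 4.45 for grn2, -6.89 for frem2a, -6.70 for frem3, -6.64 for hrh3, -6.48 for lepb and -5.30 for spon1a. Among the genes chosen in advance they were -2.84 for fgf20a, -2.28 for aldh1a2, -2.41 for msxb, -1.87 for tnc, -3.41 for fn1b, 2.59 for il1b, -1.70 for mmp9, 1.5 for mmp13a, -5.33 for shha, -2.55 for sp7 and -1.01 for evx1, that of shha resting on 3 and 9 counts in fibroblasts. Those of fgf20a and sp7 also rest on few fibroblast counts, 1 to 8 per library for fgf20a and 7 to 18 for sp7. Median log2 differences of lists were -1.96 (blastema), -2.08 (Wnt), -0.75 (Fgf), -1.02 (Hedgehog and Bmp), -1.29 (retinoic acid), -1.44 (osteoblast), -0.78 (joint and patterning), -1.87 (matrix), -1.40 (fibroblast), 1.07 (leukocyte), -0.83 (endothelium) and 0.57 (erythrocyte).

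The responses of batch 1 and batch 2, as labelled, differed for 9939 genes by the same kind of test. Log2 differences (batch 1 minus batch 2) were 17.39 for lepb, 15.82 for cmn, 14.48 for f5, 12.94 for adam8a, 12.23 for tnc, -12.34 for mpeg1.3, -10.98 for foxn1, -10.71 for snai3, -10.52 for plp1b and -10.44 for krtt1c19e. For other genes chosen in advance they were 7.59 for fgf20a, 4.93 for aldh1a2, 1.57 for msxb, 8.98 for fn1b, 2.21 for mmp9, 5.39 for mmp13a, 7.76 for shha, 0.80 for sp7, -1.33 for evx1, 10.28 for tph1b, 6.05 for mki67 and 7.74 for ccnb1. With the groups of batch 2 exchanged, many turned or shrank: lepb -3.86, cmn -2.69, f5 -5.22, adam8a -2.05, tnc 0.53, mpeg1.3 4.70, foxn1 3.27, snai3 5.64, plp1b 2.27, krtt1c19e 3.22, fgf20a -4.09, aldh1a2 0.58, fn1b -3.66, mmp9 0.35, mmp13a -3.43, shha -0.10, evx1 1.63, tph1b -1.0, mki67 0.68 and ccnb1 0.69, while msxb (2.05) and sp7 (4.82) grew.

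Blastema and cell cycle genes were higher in the libraries labelled 0 dpa of batch 2 than in those labelled 1 dpa. Against labels that are right, with uninjured fins of this batch carrying injury genes, stand 9 of 16 blastema genes more than 2-fold above every uninjured whole-fin library of the other batches (lepb 92.5-fold, tnc 32.5-fold), although the bound of 9 was set after the values were seen and 7 genes were not above it. All 6 libraries were nearest to a library of the other class over 10946 genes, those labelled 0 dpa reaching a Spearman correlation of 0.948 to 0.954 with the 2 dpa fin and at most 0.871 with uninjured fins. The planned test, the median of the early wound list, gave -0.032, which is near 0 with members going both ways and alone decides nothing. A candidate explanation is that the groups of batch 2 are exchanged in the labels, as the names of the deposited data also have it; the data cannot show where an exchange arose, and a planned difference between the pools that the labels leave out stays open.

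The 6 libraries of batch 2 make 10 splits into groups of 3, too few for a share under 0.05. Only the real split, 1 of the 10, gave 9711 genes; the highest of the other splits gave 0 by edgeR, with 10 to 32 genes at an unadjusted p under 0.05, 0 by limma-voom and at most 1 by DESeq2.

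In sorted fibroblasts stress and epidermal genes fell at 4 dpa, as both lists did in unsorted fins (medians -1.26 and -1.26). The difference between tissues was not called for either list (camera adjusted p = 0.154 and 0.165). Single stress genes did differ, with 11 of 27 more negative and 4 more positive in fibroblasts. In unsorted fins of batch 1 hsp70.1 stood at 2.8 ± 0.681 CPM at 0 dpa and 2.36 ± 0.293 CPM at 4 dpa. The gene lepb was not called between fibroblasts of uninjured fins and those at 4 dpa. That test recovered 0% of simulated changes of 0.5 and 46.2% of changes of 1 (log2). The epidermis list had a median of -1.76 over 38 genes, and krt5 stood at 18582 ± 12794 CPM at 0 dpa and 3023 ± 5.66 CPM at 4 dpa, so epidermal cells or their free RNA, in amounts that differ between the groups in spite of the sort, may account for a part of the fall of keratins. The stress list had a median of -2.08. Its member hsp70.1 reached 55106 CPM in sorted 0 dpa cells and 8083 CPM in sorted 4 dpa cells, against at most 28 CPM in any whole-fin library. Both sorted groups thus stood far above whole fins. A stronger dissociation or heat stress of the 0 dpa group may contribute, but a fall of these genes during regeneration itself stays open. Enrichment of fibroblasts alone is argued against as the source of lepb in uninjured sorted cells, since lepb was 1172-fold (685 to 2201) above the 3 wild-type whole-fin libraries at 0 dpa of batches 1 and 3 while the fibroblast list had a median ratio of 4.96 and a highest ratio of 21.6 (twist1a); this leaves out the libraries labelled 0 dpa of batch 2, whose lepb (39.1 CPM against 222 CPM in the sorted cells) would put the ratio inside the range of that list. Induction of lepb during dissociation and sorting, or in fins that had regrown after an earlier amputation, was not tested and stays open, as does a true state of the uninjured fibroblast.

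With the LEN deletion lepb was 450-fold lower at 2 dpa. A generally weaker injury response of that size is argued against by the slope of 0.929 of the deletion response on the wild-type response, and lower depth by a ratio of total gene counts of 0.976. With 1 library per genotype and time, a difference between these pools of fish other than the deletion cannot be told apart from its effect. Loss of lepb induction through the missing enhancer remains a hypothesis that these single libraries leave open. The lower immediate-early genes of the same library (fosb at -2.90, nr4a1 at -2.74) show that the pools differed in more than lepb.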

How the results depend on the processing

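The exchange of the batch 2 groups was chosen after the data were seen; the other alternatives were planned. Of 5024 values recomputed, 4900 kept their direction and side of the threshold or stayed within the main value's margin, 68 fell below the threshold, 28 passed it and 28 moved; values of single genes under the exchange are not among these, and several turned, such as lepb (17.39 to -3.86), f5 (14.48 to -5.22) and mpeg1.3 (-12.34 to 4.70). Of 3655 values of named genes 43 fell below the threshold and 6 passed it, and of 770 values of lists 25 and 22. Of 136 counts of called genes 5 moved by over 1.5 times. Leaving out each replicate gave 6273 to 7898 called genes for whole fins at 4 dpa, 9337 to 9719 for batch 2 and 9571 to 9858 for the difference between batch 1 and batch 2. For fibroblasts the range was 3827 to 7525, the lowest without replicate 1 and the next lowest, 4026, without replicate 2 of the 4 dpa group. For the fibroblast and whole-fin difference it was 2971 to 5167, the lowest without replicate 1 of the 4 dpa fins. Where this leaves 1 library in a group, it is assumed to vary like the others. Fewer samples are part of the cause where the number of calls fell, but do not account for a rise. In fibroblasts the number rose without either 0 dpa replicate and fell without either 4 dpa replicate. The 0 dpa fibroblast pair differed more (chi-square per degree of freedom 121) than the 4 dpa pair (41.4). Exchanging the groups of batch 2 reduced the difference between batch 1 and batch 2 from 9939 to 6381 genes. At 2-fold or more it went from 7520 to 2939 genes. The exchange turns the sign of the batch 2 response, so the drop reflects responses that were opposed as labelled (Pearson r -0.644 across genes). Of the original calls 5394 were called and 6083 changed sign.

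For whole fins at 4 dpa, batch 2, fibroblasts and the differences between tissues and between batches, in that order, DESeq2 called 6977, 9612, 6302, 4314 and 9886 genes, limma-voom 7804, 9757, 6526, 4437 and 9972, no expression filter 7893, 10040, 6449, 4422 and 10101, library-size scaling 7844, 9640, 6673, 3829 and 9743, and 1 fit of all replicated groups 8022, 9363, 8247, 5640 and 9590. Library-size scaling changed the sign of 333 of the calls of whole fins at 4 dpa. Its all-gene medians were 0.16 in batch 2 (55.5% higher; 0.06 with TMM) and 0.27 for the difference between batches (0.06 with TMM). With the replicate number as a block the counts were 7757, 9522, 6475, 4503 and 9749. Same-numbered libraries did not deviate together (correlation of deviations 0.048 for whole fins at 4 dpa, -0.069, -0.076 and 0.032 in batch 2 and 0.069 for fibroblasts), so the numbers do not pair the samples. Of the main calls 7607, 9453, 6291, 4250 and 9692 stayed called with the block. Among named genes, and among lists of the 3 comparisons of times, it ended the calls of the matrix list of batch 2 (adjusted p = 0.052) and of il1b in the tissue difference (0.0798). For single libraries the lepb ratios were judged the same under both other scalings and the prior count of 0.5. Among percentiles of lists 16 of 88 moved with the mean in place of the median, such as that of osteoblast genes at 2 dpa in wild type (79.7), and 7 of 375 single-library ratios moved beyond their counting interval. In values not called in the main test, a call appeared for il1b (0.0293 to 0.908) and evx1 (0.0236 to 0.924) at 4 dpa, il1b in batch 2 (0.0369 to 0.589), and aldh1a2 (0.00366 to 0.274) and lepb (0.0149 to 0.905) in fibroblasts, given as ranges of adjusted p. The leukocyte list at 4 dpa (0.023 to 0.314), the interferon list of batch 2 (0.029 to 0.204) and, in fibroblasts, the matrix (0.00499 to 0.364), interferon (0.0164 to 0.102), leukocyte (0.000548 to 0.219, median 1.26 without replicate 2 of 0 dpa) and joint lists (0.0456 to 0.444) did so too. The calls of kdrl (3.10e-05 to 0.0782) and sox10 (1.09e-06 to 0.0589) in fibroblasts ended without replicate 1 of 4 dpa, and that of sp7 in the difference between batches (0.00482 to 0.0866) without any of 3 single libraries. Beyond changes that follow from fewer samples, the cause was not tested. Depth limits the lowest genes: lepb at 0 dpa in whole fins and fgf20a and shha in fibroblasts rest on few counts.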

Other observations

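The tests here were chosen after the results were seen, apart from the single-library ratios and percentiles, which were planned. Immune genes stood apart in the LEN deletion libraries. At 0 dpa leukocyte genes had a median log2 ratio (deletion over wild type) of 0.59 and interferon response genes of 0.49, both above all 10000 matched random lists, and pigment (0.37, percentile 99.95) and osteoclast genes (0.30, percentile 99.8) lay high too. Epidermal (-0.25) and stress genes (-0.29) lay below all random lists. At 2 dpa leukocyte (0.24) and interferon genes (0.34) were again above all random lists, and stress genes (-0.30, with 8 of 26 members more than 2-fold lower) again below. Epidermal genes lay on the other side there (0.07, percentile 99.9), pigment genes at percentile 98.9 and osteoclast genes in the middle (percentile 49.6). Cell cycle genes had a small median of 0.09 at percentile 100 and early wound genes one of -0.10 at percentile 0.04. These are values of 1 library per genotype and time. Percentiles take no account of list members that vary together, and for leukocyte genes camera estimated a correlation of 0.379 in whole fins at 4 dpa.

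With the groups of batch 2 exchanged, the 4 dpa response of batch 1 had more bone and matrix transcript than that of batch 2: col10a1a (log2 difference 9.13), sgms2 (7.74), ifitm5 (7.57), cd81b (7.19) and fads2 (7.0) led, and sp7 differed by 4.82. More negative were the intestinal-type cadherin gene cdh17 (-7.67), krt93 (-7.52), trpn1 (-6.57), krt94 (-6.20) and f5 (-5.22), and also fgf20a (-4.09), lepb (-3.86), fn1b (-3.66) and mmp13a (-3.43). Lists are given with their median, camera adjusted p and adjusted p with an estimated correlation. More positive in batch 1 were osteoblast (2.53, 1.63e-23 and 0.0026), matrix (1.99, 8.07e-21 and 0.0647), fibroblast (1.48, 3.83e-09 and 0.0647) and endothelial genes (1.23, 3.19e-06 and 0.119). So were joint (0.92, 0.000451 and 0.168), leukocyte (1.1, 0.00316 and 0.644), Wnt (0.83, 0.00429 and 0.258), Hedgehog and Bmp (0.80, 0.018 and 0.311), pigment (1.05, 0.0196 and 0.667) and blastema genes (1.32, 0.0367 and 0.168). Epidermal (-1.05, 4.61e-11 and 0.0647), glycolysis and hypoxia (-0.81, 0.0022 and 0.258) and stress genes (-0.45, 0.0205 and 0.644) were more negative. The other lists, among them cell cycle (0.09, 0.55 and 0.895) and early wound genes (-0.25, 0.433 and 0.867), were not called, and with the estimated correlation only the osteoblast list was. These values hold only if the groups of batch 2 are exchanged, and batch and time cannot be told apart in them.

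Across genes, which are not independent replicates, the wild-type ratio of 2 over 0 dpa in batch 3 had a Pearson r of 0.760 with the 4 dpa response of batch 1, of 0.608 with that of fibroblasts and of -0.738 with that of batch 2 as labelled.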
